A study of Caenorhabditis elegans with 10 samples.

How the data were processed

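Small RNA was sequenced from whole Caenorhabditis elegans of the Bristol N2 strain in the first larval stage (L1), collected 1, 2, 4, 6 and 8 h after the start of treatment with alpha-amanitin, an inhibitor of RNA polymerase II. Each hour had 2 libraries, 1 in each of 2 replicate series, which gave 10 libraries in all. RNA was extracted with TRIzol and libraries were made with the TruSeq small RNA kit, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels name no untreated series and no spiked-in RNA. A slope is therefore relative to the other miRNAs of the same library, and an effect of the drug cannot be separated from that of time.

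The deposited table gave log2 values of 368 miRNA arms from 218 hairpins. The authors scaled each library to about the same total and took the log2 of the normalized reads plus 1, as read from the values of the table. CASAVA 1.8.0 and Bowtie 0.9.9.1 are named in the submitters' processing notes, and the role of each, the genome build and the miRNA annotation are not given in the sources used here. The deposited sequence files gave the count of each distinct read of 14 to 50 nt, with no normalization by the authors seen in the values, which were whole numbers with a different total in each library. The 5 table columns of series 1 were matched to single samples by name, and those of series 2 to their hour. The description labels of 4 replicate 2 samples give another hour than their titles, and the hours of the titles were used. In the alternative with the description hours, each series 2 column took the description hour of the sample titled with its hour. This was done even where the column name gave another hour, so for the deposited table no label names those hours. As a check, the ratio of table depth to reads of 18 to 27 nt in series 2 lay between 0.87 and 0.883 with the titles and between 0.746 and 1.02 with the descriptions, and 1 of 120 pairings had a spread as low.

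The low values of the table rose in steps, which gave what 1 read was worth in each column. Between 86.6% and 93.2% of the values up to 20 reads were whole within 0.1 read, and the rest were not. 3 sets of arms had identical values in every column, among them miR-44-3p and miR-45-3p, so their reads could not be told apart. All pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 14.31 over 5216 sequences, and each library was counted as 1 replicate. Pairs of the same hour, which join the 2 series, had at least 305, and pairs of different hours within a series at most 169.8. The series thus differed more than the hours within a series did.

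Slopes of the log2 values on hours were tested with limma 3.58.1 (eBayes with trend) in R 4.3.3, without a block, after arms with a mean below the 0.25 quantile were left out, which kept 276 arms. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. A fold change is on the scale of normalized reads plus 1, which understates the change of low arms. An apparent half-life is 1 divided by the slope in log2 per h, and is relative to the other miRNAs. It takes the rate as constant over the hours sampled. The passenger was the arm of a hairpin with the lower mean over all libraries. The median log2 ratio of passenger to guide in each library was correlated with hours by a two-sided permutation test with 100000 resamples, and by an exact permutation test within each series. Lists of miRNAs were tested with limma's camera (correlation of 0.01) and fry. The lists and the rule for named miRNAs were fixed before the data were examined. The rule took, among arms with an adjusted p under 0.05 and the same sign in both series, the 15 with the most negative and the 10 with the most positive slope, the other arm of each, and let-7, lin-4, lsy-6, miR-1, miR-35, miR-60, miR-71, miR-77, miR-85, miR-124, miR-235 and miR-58. As 7 arms had a positive slope past the threshold, all 7 were named.

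The numbers of the replicates pair the samples across hours: over the 10 pairs of hours, the differences between the series correlated across arms with r between 0.235 and 0.658. The pairing comes from this check and from the replicate numbers in the titles. The file names place the 2 series on different flow cells, and both libraries of an hour carry the same index, so index and time cannot be told apart.

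No genome sequence or mature miRNA sequences were given. The planned counts of miRNAs from the sequence files and the planned analysis of 3' end additions were not run. The slopes of the deposited table took their place for the named miRNAs, the lists, the strand ratio and the agreement of the series, and the classes of small RNA were set by read length and 5' base. Positions of hairpins are from the WBcel235 annotation of Ensembl release 115, in which 207 of 218 hairpins were found by name. Sequences of 18 to 27 nt with a mean of at least 50 reads were tested with edgeR 4.0.16 (quasi-likelihood test), with DESeq2 1.42.0 as an alternative. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.

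The tests were run on simulated data first. With 60 of 276 arms changed in 50 simulations, limma recovered 50.5% of arms with a slope of 0.1 log2 per h, 80.6% at 0.2 and 92.7% at 0.3, and 4.64% of its calls were false. With 200 of 5216 read sequences changed, edgeR recovered 0% at 0.1 log2 per h, 6% at 0.2, 18% at 0.3 and 54% at 0.5 in 1 simulation, and 9.30% of its calls were false. The simulated noise was independent between features and libraries, with no difference between the series, and rises and falls were equally many. In the real libraries the series differed and falls outnumbered rises, so these rates may not hold for them. Alternatives were other pseudocounts, no filter, median centring, each library left out, a replicate block, the hours of the description labels, other list tests and other tools. Intervals of read counts cover counting error alone.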

Results

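The series followed miRNA levels in L1 worms over 8 h of alpha-amanitin, with the stated aim of measuring decay rates. The sequence files held between 14951863 and 23775347 reads per library. Series 1 was deeper than series 2 at each of the 5 hours. The most abundant miRNA was miR-228-5p, which took between 16.8% and 26.7% of the normalized reads of a library.

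Which miRNAs changed relative to the rest during the block of transcription was the main question. Passenger strands made up most of the arms that fell. The passenger miR-72-3p went from 876 ± 258 normalized reads at 1 h to 179.9 ± 46.5 at 8 h (SD, n = 2 at each hour), 4.82-fold lower. Its guide miR-72-5p was 1.15-fold higher at 8 h, and the slope of the guide was not called (limma adjusted p = 0.532). The passenger miR-228-3p went from 2835 ± 319 to 583 ± 5.73 normalized reads, 4.84-fold lower. Its guide miR-228-5p stood at 1.02-fold of its 1 h level, and the slope of the guide was not called (limma adjusted p = 0.781). The rise of miR-2214 ran the other way: miR-2214-5p went from 4.33 ± 0.626 to 215 ± 80.5 normalized reads and miR-2214-3p from 6.14 ± 3.18 to 60.5 ± 16.97.

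Of 276 arms tested, 53 had a slope past the threshold, of which 46 fell and 7 rose, and all 53 had the same sign in both series fitted alone. The median slope of the tested arms was -0.021 log2 per h. Median centring adds 0.058 log2 per h to each slope, or 0.41 log2 over 7 h, and then 27 arms fell and 45 rose. Of the 46 arms that fell, 27 were still called as falling after centring, and all 7 that rose were still called as rising. Direction for arms with small slopes therefore depends on the scaling. With the 1 h libraries left out 22 arms were called, and with the 8 h libraries left out 36, both chosen after seeing the data.

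**Figure D1:**
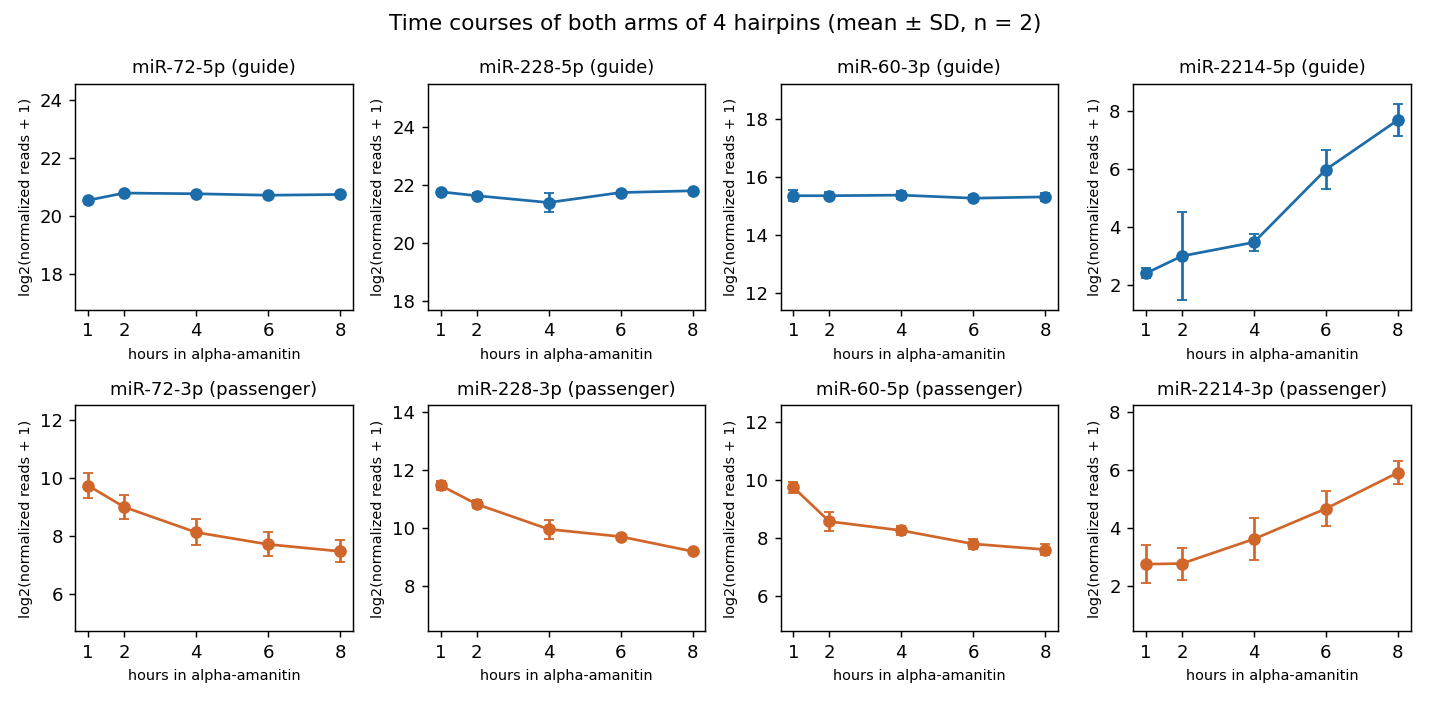
Mean log2(normalized reads + 1) ± SD (n = 2) at each hour for the guide (top row) and passenger (bottom row) of miR-72, miR-228, miR-60 and miR-2214; every panel spans the same log2 range. The passengers miR-72-3p, miR-228-3p and miR-60-5p fell while their guides were not called, and both arms of miR-2214 rose.

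The steepest fall was that of miR-1824-3p, at -0.35 ± 0.077 (SE) log2 per h (limma adjusted p = 0.00495), an apparent half-life of 2.82 h with a 95% interval of 1.92 to 5.35 h. Its level was low, 31.9 ± 11.2 normalized reads at 1 h and 5.26 ± 3.96 at 8 h. For miR-72-3p the slope was -0.31 ± 0.047 log2 per h (limma adjusted p = 0.000513) and the apparent half-life 3.18 h. The slope of miR-228-3p was -0.31 ± 0.030 log2 per h (limma adjusted p = 4.01e-05), with an apparent half-life of 3.25 h and an interval of 2.68 to 4.12 h. Such a half-life takes the rate as constant. Up to 4 h and after it, miR-72-3p had rates of -0.54 and -0.16 log2 per h, and miR-228-3p -0.50 and -0.19. In a comparison chosen after seeing the data, neither pair of rates was called as different (limma adjusted p = 0.441 and 0.210). Of the 46 arms that fell, 30 had the more negative rate up to 4 h. The passenger of miR-237, a relative of lin-4, fell 3.92-fold by 8 h and miR-60-5p, whose guide is abundant in the intestine, fell 4.44-fold. Further passengers among the 15 steepest were miR-57-3p (3.08-fold lower at 8 h), miR-45-5p (3.94-fold), miR-43-5p (3.43-fold), miR-64-3p (3.45-fold), miR-790-3p (3.28-fold), miR-4813-5p (3.97-fold), miR-81-5p (2.99-fold), miR-80-5p (2.76-fold) and miR-41-5p (2.25-fold). Over all 46 arms that fell, apparent half-lives ran from 2.82 to 18.2 h with a median of 5.33 h, and 8 were under 4 h. These values depend on the scaling: after median centring the 27 arms still called as falling had 3.37 to 10.7 h with a median of 6.54 h, and 2 were under 4 h. The call of miR-41-5p ended without replicate 1 at 2 h or without replicate 2 at 1, 2, 6 or 8 h, with slopes over the 10 fits that leave out 1 library between -0.27 and -0.15 log2 per h, and after median centring (limma adjusted p = 0.109). It also ended in the comparison of 8 h with 1 h, from which its fold comes (limma adjusted p = 0.198).

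The guides of these hairpins were not called. Among them, miR-237-5p had a slope of 0.027 ± 0.025 log2 per h, miR-60-3p -0.0094 ± 0.016, miR-57-5p 0.017 ± 0.012, miR-64-5p -0.022 ± 0.023, miR-790-5p 0.024 ± 0.021, miR-80-3p 0.0064 ± 0.021 and miR-81-3p 0.0021 ± 0.024, each ± SE. After median centring the guides miR-1824-5p, miR-45-3p, miR-790-5p, miR-80-3p, miR-72-5p and miR-57-5p were called as rising (limma adjusted p = 0.0101, 0.0151, 0.0272, 0.0299, 0.0413 and 0.0426), the steepest of them miR-1824-5p at 0.22 log2 per h (0.16 in the table as scaled). The reads of miR-45-3p could not be told apart from those of miR-44-3p. Among 63 guide or single arms with a mean log2 level of at least 12, 3 fell, 1 rose and 52 had a 95% interval of the slope within 0.1 log2 per h of 0. After median centring, which turns the median slope of all tested arms positive, 0 of these 63 fell and 23 rose by limma. Then 29 had such an interval, so whether they were steady depends on the scaling.

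Guides that fell were 5 of 142. The most marked was miR-2216-5p, in an intron of gmps-1 (WBcel235, chromosome II, 10867116 to 10867172, minus strand). Its slope had a limma adjusted p of 9.96e-05. It was 3.18-fold lower at 8 h (limma adjusted p = 0.00221 for 8 h against 1 h). Its other arm miR-2216-3p was near 2 normalized reads at 1 h. The other guides, named after their values were seen, were miR-5592-3p, 2.28-fold lower from 7.88 normalized reads, and the abundant miR-40-3p, miR-54-3p and miR-37-3p, with slopes of -0.058, -0.057 and -0.055 log2 per h. After median centring the slopes of miR-40-3p, miR-54-3p and miR-37-3p were 0.00047, 0.00090 and 0.0032 log2 per h, so their fall rests on the scaling of the table. The call of miR-5592-3p ended after median centring (limma adjusted p = 0.109), in the comparison of 8 h with 1 h (limma adjusted p = 0.102) and without replicate 2 at 1 h or 8 h, that of miR-40-3p without either library at 1 h or replicate 1 at 8 h, and that of miR-37-3p without either library at 8 h or replicate 2 at 1 h, with highest adjusted p-values by limma of 0.0632, 0.0601 and 0.0890.

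Arms that rose came from 3 groups of hairpins. The gene mir-2214 lies in an intron of B0361.11 (WBcel235, chromosome III, 7278715 to 7278778, plus strand, same strand as its host), and its arms rose by 0.76 ± 0.086 (miR-2214-5p, limma adjusted p = 7.67e-05) and 0.46 ± 0.061 log2 per h (miR-2214-3p, limma adjusted p = 0.000205). The related miR-1829a-3p, miR-1829b and miR-1829c rose by 0.13 ± 0.033, 0.14 ± 0.038 and 0.076 ± 0.020 log2 per h. They lie in introns of gas-1, F20D1.3 and piki-1 on the X chromosome, and reads of such similar miRNAs are uncertain where the counting could split them. The intergenic X-linked miR-239a-3p and miR-239b-5p rose by 0.10 ± 0.021 and 0.23 ± 0.071 log2 per h. The other arms miR-239a-5p and miR-1829a-5p, with slopes of 0.18 and 0.091 log2 per h, were not called, but passed the threshold with the replicate block (limma adjusted p = 0.0205 and 0.0456). The call of miR-239b-5p (limma adjusted p = 0.0424) ended without replicate 1 at 2, 6 or 8 h or replicate 2 at 1, 2 or 4 h (slopes of 0.17 to 0.27 log2 per h over the 10 fits). Without replicate 1 at 1 h the calls of miR-1829a-3p, miR-1829b and miR-1829c ended, and that of miR-1829b also without replicate 2 at 1 h or 8 h, with highest adjusted p-values by limma of 0.0617, 0.0716 and 0.0653. With the hours of the description labels for replicate 2, miR-239b-5p and miR-1829b were not called (slopes of 0.16 and 0.13 log2 per h, limma adjusted p = 0.2502 and 0.0591), while miR-1829a-5p was (0.10 log2 per h, limma adjusted p = 0.0238).

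Of the miRNAs chosen before the data were examined, no guide or single arm was called. The set as used held no passengers. Of the passengers of the same hairpins 3 fell: miR-60-5p, miR-71-3p (-0.16 ± 0.034 log2 per h, limma adjusted p = 0.00491) and miR-1-5p (-0.11 ± 0.027, limma adjusted p = 0.0146). The passengers miR-35-5p, miR-58-5p, miR-85-5p, miR-124-5p and miR-235-5p were tested as well and were not called. After median centring neither miR-71-3p nor miR-1-5p was called, and the call of miR-1-5p ended without replicate 2 at 8 h (limma adjusted p = 0.0596). The heterochronic miRNA let-7-5p had 12.97 ± 1.503 normalized reads at 1 h and 14.3 ± 7.66 at 8 h, and lin-4-5p had 62.2 ± 15.3 and 82.3 ± 10.2. The slope of the muscle miRNA miR-1-3p was -0.059 ± 0.025 log2 per h (limma adjusted p = 0.129), and that of the embryonic miR-35-3p was -0.062 ± 0.029 (limma adjusted p = 0.162). For the neuronal miR-124-3p and lsy-6, slopes were -0.0022 ± 0.031 and -0.018 ± 0.021 log2 per h. The values of miR-71-5p, miR-235-3p, miR-58-3p, miR-77-3p and miR-85-3p were -0.021, -0.0038, 0.039, 0.014 and -0.018 log2 per h. Of these guide and single arms miR-58-3p alone was called after median centring (0.097 log2 per h, limma adjusted p = 0.00421).

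How the 2 strands of a hairpin differed was asked with the ratio of passenger to guide. Of 101 passengers tested, 41 fell, 3 rose and 57 were not called, and of 142 guides 5 fell, 2 rose and 135 were not. In 101 hairpins with both arms tested, the passenger fell with the guide not called in 40, both arms fell in 1, and the guide alone fell in 4. After median centring 26 passengers fell and 4 rose, while 1 guide fell and 33 rose. The 33 hold both miR-44-3p and miR-45-3p, which have identical values. The median log2 ratio over the hairpins went from -3.9 in replicate 1 and -4.03 in replicate 2 at 1 h to -4.91 and -5.15 at 8 h, and a scaling of the library does not move a ratio within a hairpin. This median ratio fell by 0.14 log2 per h. A different hairpin can hold the median in each library. Hairpin by hairpin, the passenger slope lay below the guide slope in 78 of 101, with a smaller median difference of -0.077 log2 per h. The correlation of the median ratio with hours across the 10 libraries was Pearson r = -0.908 (permutation p = 0.00028) and Spearman rho = -0.960 (permutation p = 0.00012). Without the 2 libraries at 8 h r was -0.921. Within series 1 r was -0.849 (exact permutation p = 0.0417) and within series 2 it was -0.966 (exact permutation p = 0.0167).

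**Figure D2:**
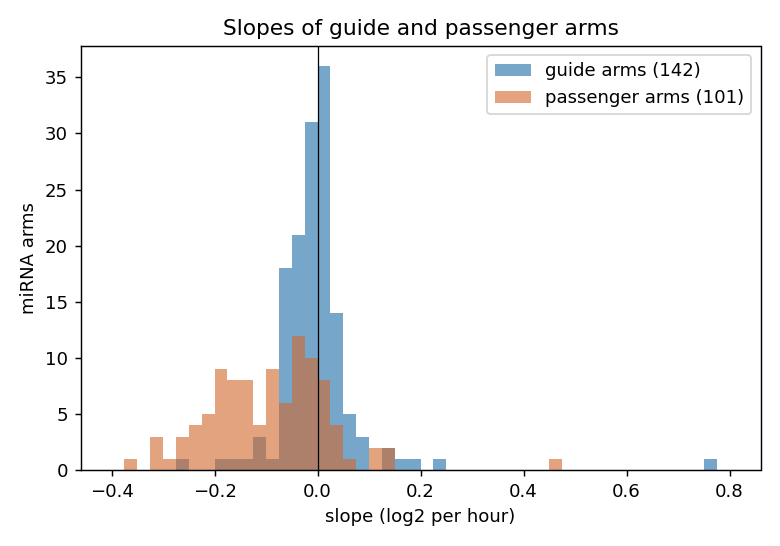
Histogram of the slopes (log2 per hour) of 142 guide arms and 101 passenger arms. The passengers have a median slope of -0.084 log2 per h and the guides one of -0.0043.

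**Figure D3:**
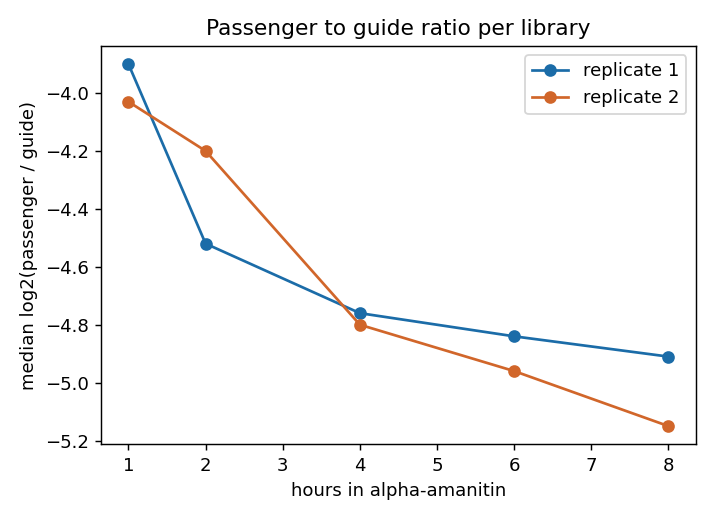
Median log2 ratio of passenger to guide over 101 hairpins (y axis) against hours in alpha-amanitin (x axis) for each library; points are libraries and lines join a series. Both series go down from 1 h to 8 h.

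Of 15 lists of miRNAs, 2 passed limma's camera, which sets a list against the other arms. By fry, which tests a list against no change, the passenger strands and the miR-51 family passed. Passenger strands lay lower with time (camera adjusted p = 5.98e-09, 49 members fell and 3 rose when adjusted over the list alone), but with an estimated correlation the adjusted p was 0.132. This list was chosen by level in these libraries, so it is no independent evidence of its direction. The miR-238 family lay higher (camera adjusted p = 0.0324, and adjusted p = 0.480 with an estimated correlation). The fry adjusted p of this family was 0.158. Of its 3 members miR-239b-5p rose, miR-238-3p had a slope of 0.028 and miR-239a-5p one of 0.18 log2 per h, and adjusted over the list alone 3 rose. The call of this family ended without replicate 1 at 8 h, or without replicate 2 at 1 h or at 2 h, which leaves 1 list, and after median centring (camera adjusted p = 0.0939).

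In the miR-35 family of embryonic miRNAs 2 of 8 members fell (miR-37-3p and miR-40-3p), also when adjusted over the list alone, and camera gave an adjusted p of 0.459. In the miR-51 family 1 of 6 fell (miR-54-3p), 1 when adjusted over the list alone, with a camera adjusted p of 0.333 and a fry adjusted p of 0.0293 in the downward direction. After median centring all 6 members of the miR-51 family had slopes above 0 and fry gave an adjusted p of 0.360 in the upward direction; 7 of the 8 of the miR-35 family were above 0 as well, and 1 of them was called. No member was called, over all arms or when adjusted over the list alone, in the let-7 (7 members), lin-4 (2), miR-58 (5), miR-64 (4), miR-72 (3), miR-44 (4) and miR-2 (4) families, the list of mirtrons (4, of which miR-1018 is intergenic in the annotation used here and miR-62, miR-1019 and miR-1020 span introns), or the neuronal (3), arrest and feeding (3) and other tissue (3) lists. After median centring members rose by limma in the let-7 (2), miR-58 (2), miR-64 (1), miR-72 (1), miR-44 (3) and miR-2 (2) families and in the mirtron, neuronal, and arrest and feeding lists (1 in each). In the miR-44 family the members miR-44-3p and miR-45-3p have identical values, so they are 1 measurement in its counts and tests. In the fit of the table as scaled, the camera adjusted p-values of these lists ran from 0.132 for the miR-2 family to 0.948 for the other tissue list. Median slopes in these lists lay between -0.025 for the miR-72 family and 0.048 log2 per h for the miR-2 family. Median, mean and camera direction differed in sign for some of the smallest, such as the miR-72 and miR-64 families.

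The 2 series gave slopes of the same sign for each called arm, with differing closeness. Fitted alone, miR-228-3p had -0.30 and -0.31 log2 per h and miR-72-3p -0.32 and -0.31, while miR-41-5p had -0.091 and -0.32, miR-43-5p -0.16 and -0.33, and miR-2214-5p 0.63 and 0.90. Among arms that were not called, signs differed for miR-124-3p (-0.025 and 0.020), let-7-5p (-0.050 and 0.095) and miR-77-3p (0.077 and -0.049). Across the 276 arms, which are not independent replicates, the slopes had Pearson r = 0.685 and Spearman rho = 0.547, and 202 had the same sign. Over 181 arms with a mean of at least 50 normalized reads r was 0.910. A slope that differed between the series was called for 0 arms by limma, with 8 at an unadjusted p under 0.05.

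**Figure D4:**
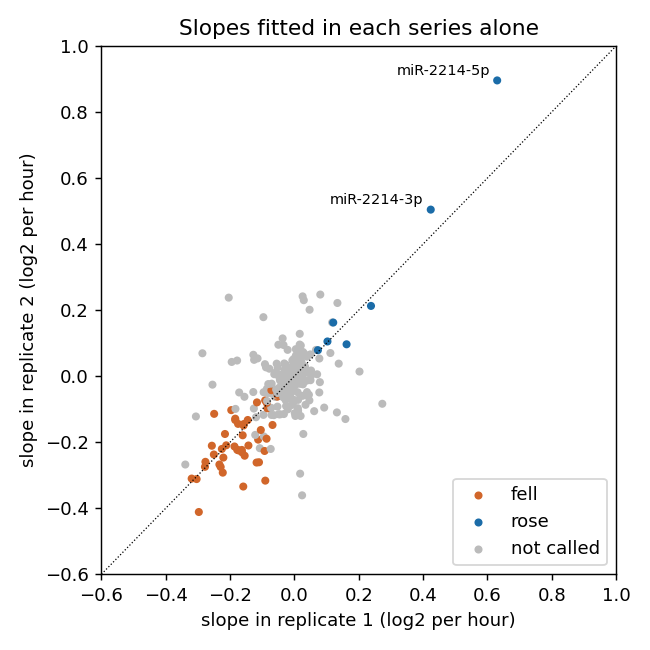
Slope of each of 276 arms (log2 per hour) in replicate 1 (x axis) against replicate 2 (y axis), coloured by whether the arm fell, rose or was not called; the dotted line marks equal slopes. The 53 called arms lie in the quadrants where both slopes share a sign.

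Reads of different length were compared as shares of all reads. Reads of 21 to 24 nt, the size of miRNAs and of 21U and 22G RNAs, made up 75.3% ± 1.86 at 1 h, 61.6% ± 0.942 at 2 h and 74.4% ± 7.93 at 8 h (SD, n = 2). The share of 14 to 17 nt reads went from 3.65% ± 0.599 at 1 h to 2.38% ± 0.375 at 8 h, with r = -0.742 (permutation p = 0.0102, adjusted p = 0.0480 over 9 classes, Spearman rho = -0.886, permutation p = 0.00178). Without the 8 h libraries r was -0.747, and within the series it was -0.931 (exact permutation p = 0.025) and -0.795 (exact permutation p = 0.0583). Reads of 22 nt with a 5' G have the form of secondary siRNAs in worms, but were not mapped, so they may be other RNA. Their share went from 0.315% ± 0.0012 to 0.252% ± 0.0222, with r = -0.754 (permutation p = 0.0107, adjusted p = 0.0480, Spearman rho = -0.739, permutation p = 0.0207). It had r = -0.779 without the 8 h libraries and -0.632 and -0.872 within the series (exact permutation p = 0.267 and 0.05). The call of 14 to 17 nt reads was kept without replicate 1 at 4 h and ended without any other library, and that of 22 nt reads with a 5' G was kept without replicate 1 at 8 h and ended without any other. With the hours of the description labels 0 classes were past the threshold. Reads of 26 nt with a 5' G have the form of another class of worm siRNAs and were likewise not mapped. Their share went from 0.303% ± 0.0577 at 1 h to 0.239% ± 0.0540 at 8 h, with r = -0.439 over all libraries (permutation p = 0.199, adjusted p = 0.447). Within the series r was -0.883 (exact permutation p = 0.05) and -0.999 (exact permutation p = 0.00833), and with the replicate block, that is the series means removed, it was -0.942 (permutation p = 0.00014, adjusted p = 0.00126). The block left the other 2 classes past the threshold, with adjusted p-values of 0.00482 and 0.0270 by permutation.

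Reads of 49 to 50 nt took 2.90% ± 0.158 of reads at 1 h, 13.5% ± 1.61 at 2 h, 9.66% ± 0.337 at 4 h, 6.59% ± 2.96 at 6 h and 3.9% ± 0.444 at 8 h. Libraries of the same hour were closer than in any other of 945 pairings (exact p = 0.00106, adjusted p = 0.00952 over 9 classes). Among the 120 pairings that join 1 library of each series, as the design does, none of the others was as close (exact p = 0.00833, adjusted p = 0.025 over 9 classes), which is the smallest p these can give and was shared by the classes of 14 to 17 and 18 to 20 nt. Both tests were chosen after seeing the data. The share of 49 to 50 nt reads had a correlation with hours of r = -0.275 (permutation p = 0.432). In every library the longest read was 50 nt, so this class may hold longer RNA whose reads end there. Reads of 28 to 48 nt also went up from 1 h to 2 h, from 8.995% to 12.57% in replicate 1 and from 10.17% to 15.71% in replicate 2. At 8 h they took 6.415% and 16.03%.

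**Figure D5:**
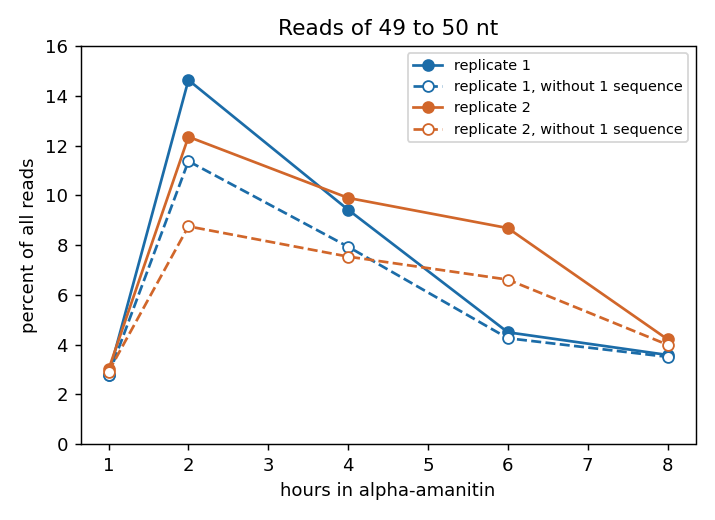
Percent of all reads that were 49 to 50 nt long (y axis) against hours in alpha-amanitin (x axis) per library, with all reads (filled points) and without the most abundant 50 nt sequence (open points). Both series peak at 2 h. No read was longer than 50 nt, so these reads may come from longer RNA.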

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

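The tests of this part were all chosen after the result was seen. A single sequence of 50 nt, the longest read length in every library, reached 3.60% of all reads in replicate 2 at 2 h. It lies outside the length of the miRNA comparisons, and there was no untreated library to set it against. It took 3.26% in replicate 1 at 2 h and 0.0106% and 0.0866% in the libraries at 1 h, so it followed the peak of 49 to 50 nt reads. That 1 sequence as the whole of the peak is argued against, since without it the share at 2 h was still 2.997 times and 4.10 times that at 1 h in the 2 series. Adapter left on the reads is argued against as well: reads with adapter sequence at 2 h were at most 0.848 times those at 1 h. What stays open is the index of the libraries, since both libraries shared 1 index at 5 of 5 hours, and a transient release of longer RNA at 2 h cannot be told apart from it. No untreated time course was analysed here, so an effect of the drug was not tested.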

How the results depend on the processing

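Tests with other pseudocounts, edgeR on recovered reads, 8 h against 1 h, the fits without the 1 h or 8 h libraries, the lists with median centring and all fits of read sequences were chosen after seeing the data. The count of called arms (53) lay between 44 and 60 with each library left out and was 61 with the replicate block, which also called miR-239a-5p and miR-1829a-5p and ended the call of 0 of the 53. It was 55 with edgeR on recovered reads (40 fell, 15 rose; 46 shared), 72 with median centring (27 fell, 45 rose; 34 shared) and 22 without the 1 h libraries. Fewer libraries enter that last fit, but the fit without the 8 h libraries, which leaves out as many, called 36 (35 shared). The number of libraries alone therefore does not account for the drop to 22. After median centring miR-40-3p, miR-54-3p and miR-37-3p turned to 0.00047, 0.00090 and 0.0032 log2 per h, as the centring adds 0.058 to each slope. With the hours of the descriptions 58 arms were called, 51 of them shared. Of 28 named arms with a call, 12 lost it under none of the settings and 19 kept it with any 1 library left out. List calls (2) were 0 with an estimated correlation, 1 with median centring (passengers) and between 1 and 2 with each library left out. By fry the passengers and the miR-51 family passed. After median centring most lists passed fry, all of them upward except the passengers. The fry adjusted p was then 0.0011 for the miR-2 family and 0.0133 for the passengers. Class calls (2) were 3 with the replicate block, 0 with the hours of the descriptions and between 0 and 1 with each library left out; the cause was not tested. With 18 to 27 nt reads as the denominator 6 classes can be formed, without that of 14 to 17 nt, and 1, that of 22 nt with a 5' G, was called. The strand ratio kept its direction and side of the threshold with 10 reads added, with guides of at least 10 times the passenger, with the hours of the descriptions, with each library left out and with the replicate block (r = -0.909), with r between -0.954 and -0.883; within series 1 alone r was -0.849. The agreement of the series (0.685) was 0.910 over arms of at least 50 reads and 0.547 as Spearman's rho. Calls of read sequences (133) were 766 with the replicate block, which takes the difference between the series out of the residual spread. The 133 come from a fit that leaves out the pairing of the samples. Without the block the calls were 413 with DESeq2 and between 50 and 125 with each library left out, and the cause of these changes was not tested. Depth limits low arms: at 12 reads or fewer, as for miR-2214 at 1 h, counting error is wide. Counts of miRNAs from the sequence files and 3' end additions were not run.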

Other observations

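The tests on scaling, on the choice of the passenger, on imbalance, on arms with at least 50 reads, on counting of miR-2214 and on the order of the hours, the edgeR test of read sequences and the comparison of early with late rates were chosen after the results were seen. The arms that fell did so on both sides of the hairpin: 26 were 5p arms and 20 were 3p arms. Of the 46 arms that fell, 30 had a more negative rate up to 4 h than after it, with medians of -0.21 and -0.15 log2 per h. The 2 rates differed for 0 arms by limma, with 32 of all arms at an unadjusted p under 0.05.

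In sequences of 18 to 27 nt, which were not assigned to genes, edgeR called 133 of 5216 (74 fell, 59 rose). On simulated data, which held no difference between the series, 9.30% of the calls of this test were false. As the numbers pair the samples, the fit with the replicate block is given beside the 133, and called 766 (523 fell, 243 rose). Without replicate 1 at 1 h or 8 h edgeR called 50 and 72, and without replicate 2 at 1 h or 2 h 63 and 85.

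Chance in the order of the hours is argued against for the number of called arms: of 100 orders, 1, the real one, gave 53 arms or more. The highest of the others gave 29, so single calls are not covered. The hours were permuted over all 10 libraries without regard to the series, and 100 orders limit how small a p can be.

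The fall of passenger strands was weighed against 3 technical explanations. Scaling of each library to the same total is argued against by the median ratio within hairpins, with a slope of -0.14 log2 per h. The median difference between the slopes of the 2 arms of a hairpin was smaller, -0.077 log2 per h. A choice of the passenger by its level is argued against by the 66 hairpins with a guide of at least 10 times the passenger. Their median ratio had the same slope to 2 decimals, -0.14. Low abundance stays partly open: guide or single arms of like level had a median slope 0.061 log2 per h above that of the passengers, but the interval of 0.029 to 0.12 reached below the 0.03 set in advance. Among arms with at least 50 normalized reads the difference was 0.14 log2 per h (interval 0.081 to 0.17), which argues against it there, for these arms in these libraries. Both intervals come from resampling arms, not libraries, so they do not measure the spread between libraries. Matched arms were used more than once, with 54 distinct arms for 101 passengers and 30 for the 57 of at least 50 reads. As a hypothesis, the more unequal the arms the faster the passenger may fall (rho = -0.447 over 101 hairpins), but rho was -0.18 among the 34 passengers of lowest level, -0.58 among the 33 in the middle and -0.63 among the 34 of highest level, so this stays open for low arms. The inequality was taken from means over all hours, which a falling passenger lowers, so a negative rho may in part be built in.

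The rise of miR-2214 was weighed against counting chance and position. Reads recovered from the table were 9 at 1 h and 416 at 8 h for miR-2214-5p, and 12 and 119 for miR-2214-3p, and the lower 95% bounds of the ratios (exact binomial) were 24.9 and 5.66, which argues against chance in counting. The other 66 arms in sense introns had a median slope of -0.023 log2 per h, and 3 of them rose and 12 fell. The interval of this median, -0.041 to -0.014, comes from resampling arms, some of which share an intron. A rise of most arms in sense introns is thus argued against. The 3 that rose were miR-1829a-3p, miR-1829b and miR-1829c, which with both arms of miR-2214 were most of the arms that rose. A median cannot tell whether position matters for such a few, so this stays open. A response of this hairpin to time or to the drug may remain as a hypothesis, and the 2 cannot be told apart without an untreated series.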
